A study of Arabidopsis thaliana with 9 samples.

How the data were processed

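Total RNA from inflorescence, leaf and root of Arabidopsis thaliana was measured on 9 arrays, 3 biological replicates per organ, with the groups and replicate numbers taken from the sample titles. Per the labels' protocols, RNA was DNase-treated, and 0.5 µg was amplified linearly into Cy3-labelled cRNA for 1-colour Agilent arrays. All plants were kept at 22 °C with 16 h of light and 8 h of dark. The ecotype labels differ between samples in a running number, while the growth protocol in the labels names Col-0 for all, and the ecotype labels were not used. The time of day of harvest was not given in the sources used here.

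Each scanner file holds 15549 spots, with 15013 gene probes and 77 negative control spots. Per the file headers, spot intensities were extracted with Agilent Feature Extraction 10.5.1.1 (protocol GE1_105_Dec08), which subtracted the background, removed spatial trends and wrote the processed signal, a linear intensity that was not normalised between arrays. A table of the whole series was also deposited by the authors, and its values were log2 signals: each column had a median of 1.41 and correlated across probes with the log2 processed signal of its array at 0.966 to 0.998. Nearly equal quartiles in all columns fit values normalised by quantiles between arrays, but how the scale was made stays unknown, since it is not given in the sources used here. The values were not centred per gene, and no direction enters because they are signals and not ratios. The table served as an alternative.

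The percentage of probes well above background was 10.6 to 39.9 per array. Because 1345 probes (8.96%) were well above background on all 9 arrays, log2 processed signals were scaled by subtracting from each array the 75th percentile over these 1345 probes. Control spots and 71 outlier spots over all arrays were left out, and 0 gene spots were saturated. Each gene spot was kept as its own probe without averaging, and the probe with the highest mean over all arrays stood for its gene. Most genes (4650) had 3 probes, 80 had 1, 289 had 2 and 58 had more. Other probes of called genes pointed the same way in 81.4% (root against leaf), 88.7% (inflorescence against leaf) and 82.1% (inflorescence against root) of cases, and in 99.0%, 98.7% and 98.6% where detected in the higher organ. Genes well above background on all 3 arrays of at least 1 organ were tested, 2124 of 5077. Probes for 3 promoter constructs were left out.

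lincRNA names are those of the array design and carry the chromosome number, and the 930 lincRNAs with a start in the probe name had the same chromosome there. The build of these coordinates is not given in the sources used here, so none were set against the reference. Of 405 gene loci named by locus code, 400 matched the TAIR10.1 gene table, from which names and coding status were taken; 3 microRNA precursors were probed under both a locus code and a microRNA name and entered as separate genes.

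Differential signal was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on means of the 3 organs over all 9 arrays), with Benjamini-Hochberg adjustment within each comparison. A call needed an adjusted p under 0.05 and at least 2-fold. All p-values of genes and lists in the text come from limma unless Fisher's exact test is named. Errors of log2 differences are standard errors of the fit. A gene was preferential to an organ when called higher than in each of the other organs. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 39 tests. Camera sets a list against all other tested genes, and 1621 of the 2124 tested genes were lincRNAs. No list was tested against the other protein-coding genes alone. By camera 17 passed, and 7 did with an estimated correlation. With fry 27 passed. Fry asks whether a list's genes move one way on balance and compares it with no other genes. The 7 that held with an estimated correlation were abscisic acid and cold or drought genes (root against leaf, inflorescence against root), jasmonate genes (inflorescence against leaf, inflorescence against root), small RNA machinery on the array (root against leaf, inflorescence against leaf) and its members fixed in advance (inflorescence against leaf).

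The comparisons, tests, named-gene rule, 12 gene lists and all alternatives other than those named in the closing part as chosen later were fixed before the data were examined. Of these lists, 8 had no member on the array (photosynthesis, floral organ identity, anther and pollen, root cell types, root nutrient uptake, phosphate starvation, cell division, reference genes), known long non-coding RNAs and heat and stress genes had 1 tested member each, microRNA precursors had 17 and small RNA machinery 6. A further 7 lists (light, clock, abscisic acid and cold or drought, embryo and seed, jasmonate, auxin, small RNA machinery) were drawn up from the gene names on the array before signals were compared, and 4 classes of the array (all microRNA precursors, annotated non-coding loci, lincRNAs, protein-coding genes) were tested in the same way, which made 13 tested lists. The named genes were those called, with all 3 arrays of 1 organ above all 3 of the other. Per comparison and direction they were the 6 largest folds among lincRNAs and 2 among other genes measured on all arrays of both organs, and the 3 and 1 largest lower bounds where the dimmer organ had no array well above background. For each organ the 3 preferential lincRNAs with the largest smaller fold were added, and list members could be named. The test for the lower bounds was at first read as covering the single representative probe and was corrected to all probes of a gene after the named genes had been seen.

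Slide and scan coincided, with replicates 1 and 2 of each organ on slide 1 and replicate 3 on slide 2, so slide was fitted as a block and each comparison repeated within slide 1. Arrays with the same replicate number deviated together from their organ means (correlations 0.141 to 0.631 over 9 pairs), which by the rule used here pairs them. Arrays of different number on the same slide had 0.190 to 0.537 and on different slides -0.586 to -0.192, so the pairing follows the slide. Alternatives covered scaling, background correction, filters, probe averaging, blocks, weights, thresholds and leaving out each array. Normexp used the median spot signal with the median local background, in place of the mean signal named in the plan, with an offset of 50.

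The fit was tested on simulated data for root against leaf with 2124 genes, 50 changed per fold size. It recovered 22%, 50%, 74% and 84% at 2-, 4-, 8- and 16-fold, none in the wrong direction, and called 1 of 1924 unchanged genes. A recovery of at least 45 of 50 at 16-fold had been set as a condition and was not met (42 recovered); estimates were unbiased (mean standardised error -0.04, 92.5% within 2 standard errors), the missed genes had a median SD of 1.41 against 0.36 for those found, and the condition was replaced by these checks. In 20 simulations without any difference, at most 2 genes were called in any comparison. All simulated noise was independent between genes and arrays, without the slide effect of the real arrays.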

Results

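RNA from inflorescences, leaves and roots of wild-type Arabidopsis thaliana (Col-0) was hybridised to a custom 1-colour array designed for long intergenic non-coding RNAs (lincRNAs), transcripts that arise between annotated genes. Each organ was represented by 3 biological replicates, 1 array each, 9 arrays in all. Leaves and roots came from 30-day-old plants in hydroponic culture. The inflorescences, bearing open flowers, buds and a few very young siliques, came from 4-week-old plants on solid medium or in a greenhouse, so that every comparison with inflorescence also compared growth conditions and age. The array held 15013 probes for 5077 genes: 4499 lincRNAs, 302 annotated non-coding loci, 177 microRNA precursors, 94 protein-coding genes and 5 loci without a match in the reference table. The protein-coding genes were chosen by the designers of the array and are not a sample of the coding genome. Genes were tested where well above background on all 3 arrays of at least 1 organ, which left 2124, of them 1621 lincRNAs. The number of arrays limits the precision of every value below.

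Between 10.6% and 39.9% of the probes were well above background per array. In inflorescence the shares were 37.8%, 37.4% and 24.1% for replicates 1 to 3, in leaf 37.2%, 10.6% and 24.8%, and in root 36.0%, 39.9% and 25%. Replicates 1 and 2 of every organ lay on slide 1 and replicate 3 on slide 2. The lincRNAs carried this difference: root arrays detected 2579, 2876 and 1509 lincRNAs but 88, 89 and 86 protein-coding genes. On leaf replicate 2, the array with the fewest, 501 lincRNAs and 71 protein-coding genes were detected. Detected on all 3 arrays of an organ were 1726 genes in inflorescence, 754 in leaf and 1845 in root. Without leaf replicate 2 the leaf count was 1918, without inflorescence replicate 3 the inflorescence count was 2760, and without root replicate 3 the root count was 2883. Across genes, correlations between arrays were 0.939 to 0.987 within an organ on the same slide, 0.915 to 0.938 within an organ across slides and 0.664 to 0.821 between organs. Genes are not independent replicates in these correlations.

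**Figure D1:**
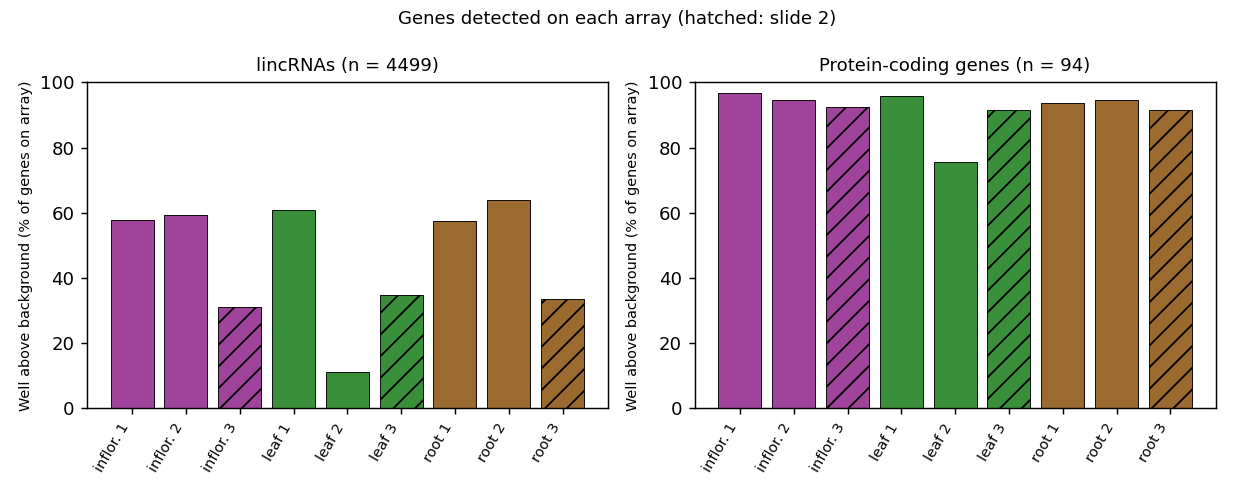
Percentage of the lincRNAs (left) and protein-coding genes (right) on the array that were well above background, 1 bar per array, coloured by organ and hatched for slide 2. In inflorescence and root fewer lincRNAs passed on replicate 3 than on replicates 1 and 2, as with 1392 in inflorescence against 2594 and 2674. In leaf 2730, 501 and 1568 passed on replicates 1 to 3. Protein-coding genes ranged from 71 to 91 over the 9 arrays.

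The first comparison asked which RNAs differed between root and leaf of plants of the same age and culture. Of the 2124 genes tested, 290 were higher in root and 216 higher in leaf by at least 2-fold, and lincRNAs made up 188 and 107 of these. The cold-responsive genes COR15A and COR15B, which encode chloroplast proteins, had the largest folds among genes measured on all arrays of both organs, 3589-fold and 2529-fold higher in leaf than in root (log2 root minus leaf -11.81 ± 0.18 and -11.30 ± 0.16, SE, n = 3 arrays per organ, limma adjusted p = 1.67e-08 for both). These folds are for the probe that stands for the gene. The probes of COR15A spanned -11.81 to -6.35 and those of COR15B -11.39 to -8.43. The root mean of COR15A was low (-5.76), so its fold is not exact. Among lincRNAs measured on all arrays of both organs, AT3TU041570 on chromosome 3 was 383-fold higher in leaf (-8.58 ± 0.16) and AT5TU074240 on chromosome 5 was 27.0-fold higher in root (4.76 ± 0.14, adjusted p = 2.43e-07). The annotated non-coding locus AT3G52748 was 110-fold higher in root.

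Among lincRNAs measured on all arrays of both organs, the next largest folds toward root were those of AT5TU070830 (log2 difference 4.08 ± 0.15), AT1TU020060 (3.94 ± 0.15), AT5TU044080 (3.37 ± 0.14), AT1TU073080 (3.21 ± 0.17) and AT1TU070170 (2.92 ± 0.21), with limma adjusted p from 6.82e-07 to 2.63e-05. For AT5TU044080, 1 of its 3 probes went the other way (-1.13). With the same limit, toward leaf AT2TU063000 (-6.70 ± 0.26), AT3TU041050 (-6.04 ± 0.35), AT2TU032020 (-5.84 ± 0.30), AT3TU062330 (-4.54 ± 0.19) and AT1TU028770 (-4.09 ± 0.13) followed AT3TU041570. The root mean of AT2TU063000 was low (-5.89), so its fold is not exact. Larger fitted folds toward root were found where leaf was measured on 2 of 3 arrays, as for AT4TU029580 (11.62 ± 0.21) and AT1TU066270 (9.86 ± 0.28). The probes of AT3TU041570 spanned -8.58 to -0.26, and 1 probe of AT2TU032020 was level (0.05). With the probes of a gene averaged, the call of AT5TU044080 was lost. The probe name of AT3TU041050 gives a start of 11776550 on chromosome 3, in a build that is not given in the sources used here. The non-coding locus AT5G07322 was 53.5-fold higher in root (5.74 ± 0.14). Where no array of the dimmer organ was well above background, a fold is a lower bound, taken against the lowest signal that was well above background on those arrays or the gene's own signal if higher. By this bound AT1TU043160 was at least 141-fold, AT1TU072870 at least 58.0-fold and AT5TU070210 at least 57.5-fold higher in root, as was LAF1, a MYB transcription factor of far-red light signalling, by at least 145-fold (adjusted p = 0.000105). In the other direction AT4TU026320 was at least 132-fold, AT5TU042690 at least 51.2-fold, AT1TU097140 at least 29.9-fold and the precursor ath-MIR850 at least 124-fold higher in leaf. All these bounds are for the probe that stands for the gene. The weakest probes of AT4TU026320, AT5TU042690 and AT1TU097140 were at -3.02, -0.58 and -1.39 on the log2 scale.

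By gene list, 8 of the 13 genes of abscisic acid signalling and cold or drought response fell in root relative to leaf, 1 rose and 4 did not pass (camera adjusted p = 2.46e-05, adjusted p = 0.029 with an estimated correlation). LTI78, also called RD29A and the 1 member on the array of the list of heat and stress genes, differed by -7.03 ± 0.19, and ABI5, a bZIP factor of the abscisic acid response, by -1.48 ± 0.18. KIN1 was not well above background on any root array. COR47 differed by -0.16 ± 0.17 (adjusted p = 0.636). The exception was AFP1, which encodes a binding partner of ABI5 and rose by 2.07 ± 0.15. Of 4 jasmonate repressor genes, 3 fell in root (adjusted p = 0.000811, adjusted p = 0.0704 with an estimated correlation): TIFY7 (-5.57 ± 0.17), JAZ10 (-1.82 ± 0.19) and JAZ6 (-1.35 ± 0.14). Of 7 circadian clock genes, 5 fell, among them CCA1 (-2.54 ± 0.19) and LHY (-1.44 ± 0.14), and none rose (adjusted p = 0.000984, adjusted p = 0.107 with an estimated correlation). PRR9 and PRR7 differed by 0.92 ± 0.14 and -0.88 ± 0.14, short of 2-fold.

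The small RNA machinery went the other way, with 3 of 11 genes higher in root and none lower (adjusted p = 0.000637, adjusted p = 0.0402 with an estimated correlation): RDR2 (1.49 ± 0.15), NRPD1 (1.46 ± 0.17) and DCL2 (1.05 ± 0.13). Its 6 members fixed in advance had 2 calls, also 2 adjusted over the list alone (adjusted p = 0.0041, adjusted p = 0.0704 with an estimated correlation). Of all 92 tested protein-coding genes, 21 were higher and 28 lower in root. Their median log2 difference was 0.2, against 0.74 for the 11 genes of small RNA machinery. Light signalling genes were called both ways, 2 higher and 5 lower of 12 (adjusted p = 0.163). The phytochrome-interacting factors PIF4 (-9.09 ± 0.18), PIL6 (-6.64 ± 0.17), PIF3 (-4.01 ± 0.15) and PIL5 (-3.21 ± 0.14) were all lower in root, and FHL, a factor of phytochrome A nuclear import, was higher (adjusted p = 6.99e-05). Of the 17 microRNA precursors fixed in advance, 2 rose and 4 fell, the same numbers adjusted over the list alone, and the list did not pass (adjusted p = 0.267). MIR172B was not well above background on any root array, MIR169A fell by 2.07 and MIR166A rose by 1.43 on the log2 scale. Over all 118 tested precursors 16 rose and 26 fell (adjusted p = 0.0288, adjusted p = 0.856 with an estimated correlation). The lists of embryo and seed genes (2 lower of 4, adjusted p = 0.116) and auxin genes (2 higher of 5, adjusted p = 0.251) did not pass. TAS4, a source of trans-acting small RNAs, rose by 1.43 ± 0.18, with leaf measured on 2 of 3 arrays, and was not called after quantile normalization.

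Calls came from limma at an adjusted p under 0.05 and at least 2-fold. With slide as a block, 381 genes were higher and 273 lower in root, and all 506 calls remained. Within slide 1, 300 were higher and 241 lower, with 453 of the 506 called, and on slide 2, with 1 array per organ and no test, 505 had the same sign. The 506 genes were called with the slide 2 arrays included, so this agreement in sign was largely set by the selection. The share of calls higher in root was 57.3%. It was 77.8% when each array was scaled to its median, 49.2% with normexp and 38.0% among genes well above background on all 9 arrays. That last filter needs a pass on leaf replicate 2, where the fewest genes passed. It thus leaves out genes dim in leaf, and its share is partly set by that selection. With slide as a block the share was 58.3%, and without leaf replicate 2 as well it was 51.6%. The balance of directions therefore depends on these choices and on that array. Under median scaling or the 75th percentile of all probes, calls were lost for ABI5, CCA1, LHY, JAZ6, JAZ10, RDR2, NRPD1, DCL2, MIR166A and MIR169A, with their directions kept, and that of DCL2 also fell short of 2-fold after quantile normalization (0.95). The median shift of the list of abscisic acid and cold or drought genes was -1.30 on slide 1 and -1.84 on slide 2, of jasmonate genes -1.62 on slide 1 with the same sign on slide 2, of clock genes -1.23 and -1.33 and of small RNA machinery 0.72 and 0.78, all past the threshold on slide 1 and with slide as a block (adjusted p up to 0.00519 and 0.00334).

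**Figure D2:**
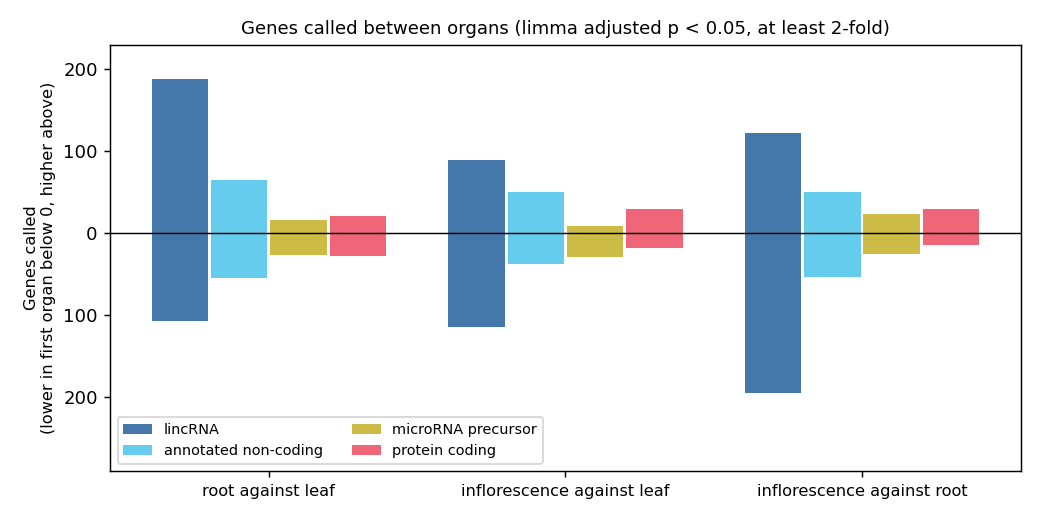
Number of genes called in each comparison, by class of RNA. Bars above 0 count genes higher in the organ named first and bars below 0 genes lower there. For lincRNAs the counts were 188 and 107 in root against leaf, 89 and 115 in inflorescence against leaf, and 122 and 195 in inflorescence against root.

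Between inflorescence and leaf, 179 genes were higher in inflorescence and 199 higher in leaf, with 89 and 115 lincRNAs. The clock gene LHY, a morning-phased MYB factor, was 45.9-fold higher in inflorescence (log2 inflorescence minus leaf 5.52 ± 0.14, SE, n = 3 arrays per organ, limma adjusted p = 1.56e-06), and the non-coding locus AT2G47895 was 51.8-fold higher (5.69 ± 0.20). MEE26, named for an embryo arrest phenotype, was at least 408-fold higher in inflorescence, and the lincRNA AT5TU080700 at least 89.4-fold. In leaf, the non-coding locus AT4G13495 was 88.4-fold higher (-6.47 ± 0.19), the precursor ath-MIR850 77.7-fold higher and ath-MIR398a, with 1 probe, at least 118-fold higher (adjusted p = 6.36e-06). The inflorescence mean of ath-MIR850 (-6.55) lay near the lowest signals well above background, so its fold is not exact.

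The lincRNAs with the largest folds toward inflorescence among those measured on all arrays of both organs were AT2TU000580 (3.56 ± 0.29), AT1TU073080 (3.55 ± 0.17), AT2TU056230 (2.91 ± 0.29), AT2TU032570 (2.79 ± 0.16), AT4TU024160 (2.66 ± 0.66, adjusted p = 0.0222) and AT5TU044080 (2.64 ± 0.14). The call of AT4TU024160 was lost without inflorescence replicate 1, 2 or 3 or leaf replicate 3. One of 3 probes went against the gene for AT2TU000580 (-1.17) and AT2TU032570 (-1.03), and 2 of 3 for AT5TU044080 (lowest -1.03). With the probes of a gene averaged, the calls of AT2TU000580, AT2TU056230, AT5TU044080, AT3TU041050 and AT3TU041570 were lost, as was that of AT2TU019750, a leaf-preferential lincRNA. AT5TU018610 was at least 65.3-fold higher in inflorescence, by 2 of its 3 probes, and AT1TU057020 at least 38.3-fold. Higher in leaf were AT4TU026320 (-4.70 ± 0.22), AT2TU063000 (-4.28 ± 0.26), AT3TU062330 (-3.91 ± 0.19), AT3TU041050 (-3.65 ± 0.35), AT5TU087180 (-3.48 ± 0.46) and AT3TU041570 (-3.32 ± 0.16), with adjusted p from 6.69e-06 to 0.00111. AT3TU040390 was at least 50-fold, AT4TU026290 at least 46.4-fold and AT5TU090930 at least 16.8-fold higher in leaf, though its call was lost with a common floor under all signals. These bounds are for the probe that stands for the gene, and the weakest probe of AT5TU090930 was at -0.78.

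Clock genes split, 3 higher and 3 lower in inflorescence of 7 (camera adjusted p = 0.872; the median log2 difference was -0.76 and the mean 1.01). CCA1 (4.70 ± 0.19) and PRR9 (3.62 ± 0.14) were higher along with LHY. PRR3 (-3.01 ± 0.14), TOC1 (-1.94 ± 0.14) and PRR5 (-1.09 ± 0.14) were lower, and the time of day of harvest was not given in the sources used here. Jasmonate genes rose, 3 of 4 (adjusted p = 3.66e-05, adjusted p = 0.0402 with an estimated correlation): JAZ10 (3.61 ± 0.19), JAZ5 (3.49 ± 0.14) and JAZ6 (1.47 ± 0.14). Small RNA machinery rose in 4 of 11 genes with none lower (adjusted p = 7.55e-06, adjusted p = 0.029 with an estimated correlation): DCL3 (1.84 ± 0.19), NRPE1 (1.75 ± 0.14), RDR2 (1.65 ± 0.15) and NRPD1 (1.57 ± 0.17), which act in RNA-directed DNA methylation. Of its 6 members fixed in advance 3 rose, also 3 adjusted over the list alone (adjusted p = 4.63e-05, adjusted p = 0.0295 with an estimated correlation). Camera compared these genes with all other tested genes, mostly lincRNAs. The protein-coding genes on the array rose too, 30 higher and 18 lower of 92. Their median was 0.54, against 0.6 for the 11 genes, so the test does not set this list apart from other coding genes.

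Genes of abscisic acid signalling and cold or drought response went both ways, 4 higher and 3 lower of 13 (adjusted p = 0.74). ABI5 (4.15 ± 0.18), AFP1 (3.01 ± 0.15) and KIN1 (2.72 ± 0.26) were higher in inflorescence, while LTI78 (-3.94 ± 0.19), COR15B (-3.44 ± 0.16) and COR15A (-3.25 ± 0.18) were lower. In light signalling 2 rose and 4 fell of 12 (adjusted p = 0.978), with HFR1 at 4.60 ± 0.57 (leaf measured on 2 of 3 arrays) and PIF4 at -3.25 ± 0.18. Of the 17 microRNA precursors fixed in advance 1 rose and 3 fell, the same numbers adjusted over the list alone (adjusted p = 0.872). MIR169A fell by 5.79, with inflorescence measured on 1 of 3 arrays, and MIR163 rose by 1.45. The tested protein-coding genes as a class rose in 30 and fell in 18 of 92 (adjusted p = 7.93e-05, adjusted p = 0.139 with an estimated correlation). Embryo and seed genes (1 higher of 4, adjusted p = 0.123), auxin genes (2 higher of 5, adjusted p = 0.263) and all 118 microRNA precursors (9 higher, 29 lower, adjusted p = 0.0633) did not pass.

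With slide as a block, 234 genes were higher in inflorescence and 278 lower, with all 378 calls kept. Slide 1 alone gave 199 and 240, with 343 of the 378 called, and 377 had the same sign on slide 2, whose arrays had entered the calls. The share of calls higher in inflorescence, 47.4%, was 61.3% with the 75th percentile taken over all probes and 74.9% with the median of each array, and these settings called 212 and 231 genes. Among genes well above background on all 9 arrays it was 30.2%, a filter that again needs a pass on leaf replicate 2 and leaves out genes dim in leaf. With slide as a block the share was 45.7%, and without leaf replicate 2 as well it was 38.6%. Under 1 or both of the scalings, calls were lost for JAZ6, TOC1, PRR5, NRPD1, NRPE1, RDR2 and MIR163, with their directions kept, and PRR5 fell short of 2-fold after quantile normalization as well. Jasmonate genes shifted by a median of 2.51 on slide 1 and 2.41 on slide 2, and small RNA machinery by 0.54 and 0.74, with adjusted p of 0.000181 and 8.81e-06 with slide as a block. The class shifts of lincRNAs (median -0.26, adjusted p = 0.123) and annotated non-coding loci (median 0.05, adjusted p = 0.123) passed with slide as a block (0.0276 and 0.0382) and with a replicate block (0.0266 and 0.0372), but not with an estimated correlation (0.879 and 0.856).

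Inflorescence and root differed in 514 genes, 226 higher in inflorescence and 288 higher in root, with 122 and 195 lincRNAs. The lincRNA AT4TU029580 was 2679-fold higher in root (log2 inflorescence minus root -11.39 ± 0.21, SE, n = 3 arrays per organ, limma adjusted p = 7.27e-08), by 2 of its 3 probes, and AT1TU066270 was 1332-fold higher in root (-10.38 ± 0.28). The probes of AT1TU066270 spanned -12.53 to -5.66. Its inflorescence mean (-6.50) lay near the lowest signals well above background, so its fold is not exact. The inflorescence mean of AT4TU029580 was low too (-5.86), and its fold carries the same limit. The lincRNA AT2TU004830 was at least 1494-fold higher in inflorescence, and the non-coding locus AT4G04077 2105-fold higher (11.04 ± 0.41). The root mean of AT4G04077 was also low (-6.11), so its fold is not exact. COR15A was 377-fold higher in inflorescence (8.56 ± 0.18), with probes from 4.16 to 8.56. LAF1 was at least 324-fold higher in root, and MEE26 at least 892-fold higher in inflorescence.

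Among lincRNAs measured on all arrays of both organs, those higher in inflorescence than in root included AT3TU041570 (5.26 ± 0.16), AT2TU000580 (4.41 ± 0.29), AT1TU028770 (4.03 ± 0.13), AT1TU015150 (3.82 ± 0.54), AT4TU024160 (3.64 ± 0.66) and AT4TU057340 (3.54 ± 0.61), with adjusted p up to 0.00403. One probe of AT3TU041570 went the other way (-0.98), and with the probes averaged its call was lost. The lowest probes of AT2TU000580 (0.01) and AT1TU015150 (0.08) were level. Root means of AT1TU015150 (-6.82) and AT4TU057340 (-5.9) were near the lowest signals well above background, so these folds are not exact. AT5TU080700 was at least 195-fold and AT5TU018610 at least 143-fold higher in inflorescence, the latter by 2 of its 3 probes (lowest -0.19). With the same limit, AT1TU066270 was followed toward root by AT1TU048160 (-7.71 ± 0.65), AT1TU070790 (-6.94 ± 0.23), AT1TU072870 (-6.23 ± 0.42) and AT1TU091960 (-5.24 ± 0.74, by 2 of 3 probes, and not called with the probes averaged), and the non-coding loci AT3G52748 (-8.22 ± 0.23) and AT5G07322 (-7.49 ± 0.14). Inflorescence means of AT1TU048160, AT1TU070790, AT1TU072870 and AT1TU091960 were -5.81, -6.35, -6.5 and -6.08, so these folds are not exact either. AT1TU043160 was at least 296-fold, AT5TU070210 at least 121-fold and AT2TU035760 at least 70.9-fold higher in root.

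All 4 jasmonate genes rose in inflorescence (camera adjusted p = 2.03e-06, adjusted p = 0.029 with an estimated correlation), from JAZ6 (2.81 ± 0.14) and JAZ5 (3.85 ± 0.14) to JAZ10 (5.43 ± 0.19) and TIFY7 (6.47 ± 0.17). Of the 13 genes of abscisic acid signalling and cold or drought response, 7 rose and none fell (adjusted p = 3.03e-07, adjusted p = 0.029 with an estimated correlation), among them COR15B (7.87 ± 0.16), ABI5 (5.63 ± 0.18) and the subunit gene NF-YA5 (3.42 ± 0.15). Clock genes had 3 higher and 1 lower of 7 (adjusted p = 0.0486, adjusted p = 0.322 with an estimated correlation): CCA1 (7.25 ± 0.19), LHY (6.96 ± 0.14) and PRR9 (2.70 ± 0.14) against PRR3 (-1.44 ± 0.14). Light signalling genes had 5 higher and 2 lower of 12 (adjusted p = 0.00589, adjusted p = 0.213 with an estimated correlation), with PIF4 (5.84 ± 0.18), PIL6 (5.38 ± 0.17) and HFR1 (6.65 ± 0.57, root measured on 2 of 3 arrays) higher. In embryo and seed genes 2 of 4 rose (adjusted p = 0.0144, adjusted p = 0.317 with an estimated correlation), 3 adjusted over the list alone. They were FUS3, a regulator of seed maturation (5.14 ± 0.36, root measured on 2 of 3 arrays), and LEC1, not well above background on any root array.

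Protein-coding genes as a class rose in 30 and fell in 14 of 92 (adjusted p = 1.14e-05, adjusted p = 0.107 with an estimated correlation), and lincRNAs lay lower in inflorescence as a class (adjusted p = 0.0287, adjusted p = 0.857 with an estimated correlation). Small RNA machinery did not pass in either list (2 of 11 higher, adjusted p = 0.421; 2 of the 6 fixed in advance, also 2 adjusted over the list alone, adjusted p = 0.291), nor did auxin genes (1 lower of 5, adjusted p = 0.626) or all 118 microRNA precursors (23 higher, 25 lower, adjusted p = 0.737). Of the 17 precursors fixed in advance 3 rose and 2 fell, or 4 and 3 adjusted over the list alone (adjusted p = 0.421). MIR398A, not well above background on any inflorescence array, was lower there, and MIR163 rose by 3.25 ± 0.16. Annotated non-coding loci as a class did not pass in any of the comparisons (adjusted p = 0.737, 0.123 and 0.291 for root against leaf, inflorescence against leaf and inflorescence against root).

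A block for slide gave 270 genes higher in inflorescence and 365 lower than in root, and kept all 514 calls. Slide 1 alone gave 235 and 310, with 463 of the 514 called, and 513 had the same sign on slide 2, whose arrays had entered the calls. Fewer genes were called with normexp (220), with a common floor under all signals (288) and among genes well above background on all 9 arrays (173). Jasmonate genes shifted by a median of 4.66 on slide 1 and 4.60 on slide 2, abscisic acid and cold or drought genes by 1.14 and 1.48, and light signalling genes by 0.58 and 0.59, with adjusted p of 8.81e-06, 1.86e-06 and 0.00556 with slide as a block. The clock list was not past the threshold after quantile normalization (adjusted p = 0.152), and the call of PRR3 was lost when arrays were scaled to their median or to the 75th percentile of all probes. LEC1 was not called in this comparison with normexp or with a common floor under all signals.

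**Figure D3:**
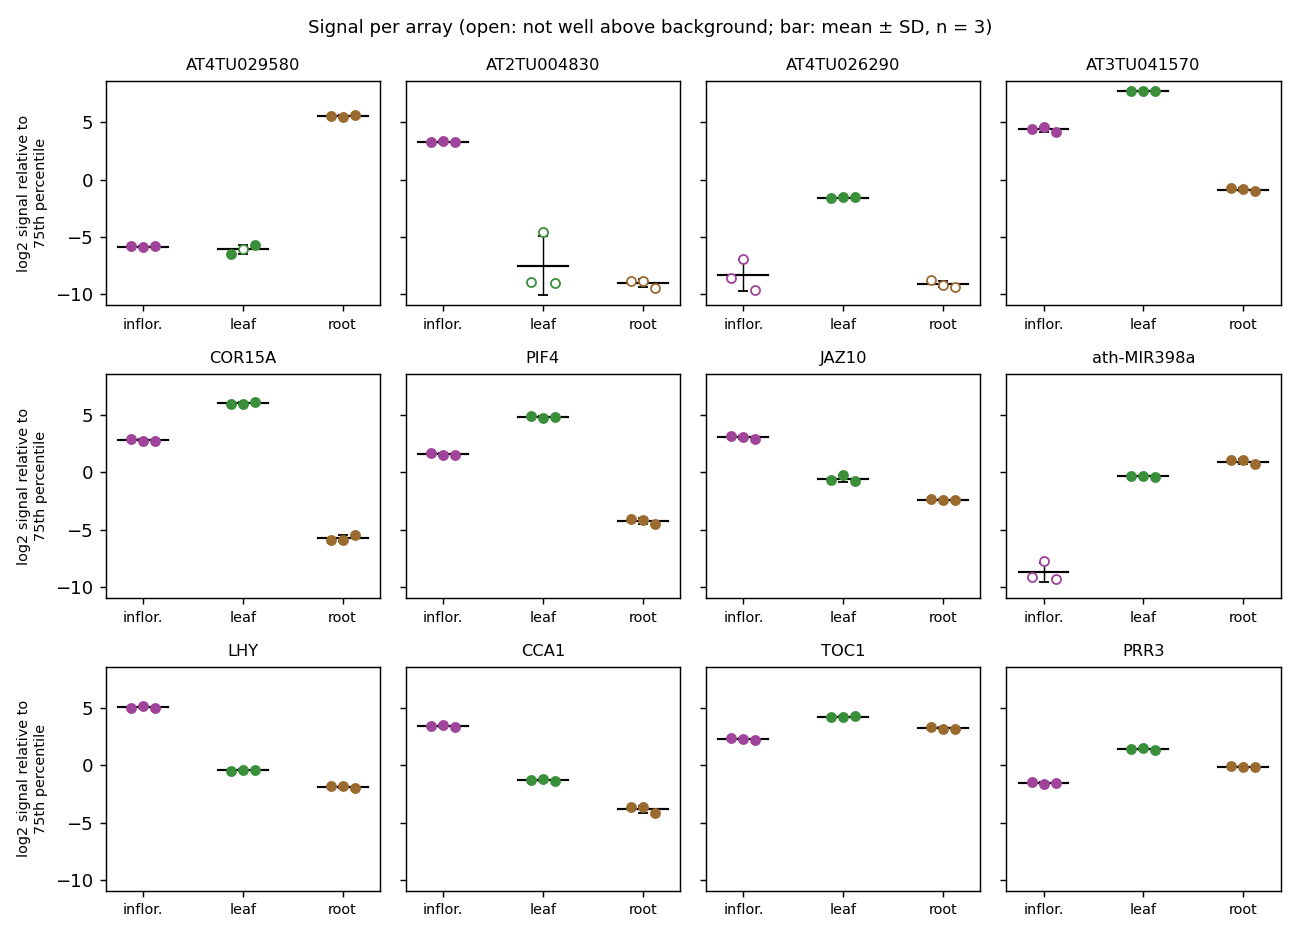
Signal of 12 genes on each array, as log2 relative to the scaling percentile of that array, by organ. Points are arrays, open where not well above background, and bars give the mean and SD of 3 arrays. AT4TU029580 averaged 5.53 in root against -5.86 in inflorescence, COR15A 6.05 in leaf against -5.76 in root, and LHY 5.09 in inflorescence against -0.43 in leaf.

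Any difference among the 3 organs was found by the moderated F test for 821 genes, and for 1268 with slide as a block. Of the lincRNAs tested, 468 (28.9%) differed, against 202 of 288 annotated non-coding loci (70.1%), 73 of 118 microRNA precursors (61.9%) and 76 of 92 protein-coding genes (82.6%). Genes higher in 1 organ than in each of the others numbered 103 in inflorescence (56 lincRNAs), 119 in leaf (66 lincRNAs) and 186 in root (126 lincRNAs). With slide as a block there were 128, 158 and 235, and within slide 1 there were 112, 141 and 194. With the 75th percentile over all probes there were 85, 56 and 142, and with the median of each array 87, 36 and 173. Whether inflorescence or leaf had more thus depends on the scaling. Independent lists would share 19.1, 20.2 and 39.3 genes, and at most 1 gene per organ was found in 20 simulations without any difference. Both comparisons behind each count used the same arrays of the preferred organ, and part of the excess over these values may come from that. The simulations drew noise independently for each gene and array, without a slide effect. They therefore do not show how many genes noise shared within a slide would give.

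Fitted folds rank the preferential lincRNAs here, though they are not exact where an organ had no array well above background. By the smaller of the 2 fitted folds, the inflorescence-preferential lincRNAs with the widest margins were AT2TU004830, at least 683-fold above leaf and at least 1494-fold above root, AT5TU080700 and AT5TU018610. In leaf they were AT4TU026290, at least 51.5-fold above root and at least 46.4-fold above inflorescence, AT2TU019750, at least 22.1-fold and 21.2-fold, and AT4TU026320. In root they were AT4TU029580, with a log2 difference from leaf of 11.62 ± 0.21, AT1TU066270, with 9.86 ± 0.28, both measured on 2 of 3 leaf arrays, and AT1TU043160. For AT4TU029580, 1 of 3 probes was lower in root than in leaf (-0.77). These bounds are for the probe that stands for the gene, and another probe was well above background on 1 or more arrays of leaf for AT2TU004830, of root for AT4TU026290 and of inflorescence for AT2TU019750. The weakest probe of AT2TU019750 was at -1.24 in root against leaf and -0.6 in inflorescence against leaf. Among preferential lincRNAs, 15 of the inflorescence group, 13 of the root group and 0 of the leaf group had no probe well above background on any array of the other organs. A gene detected in leaf alone had to pass on leaf replicate 2. The lowest signal well above background there was 29.8, against 3.9 to 6.8 on the other arrays, so the leaf count is not comparable. Without that array and with slide as a block, 148, 248 and 257 genes were preferential to inflorescence, leaf and root.

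Calls were less frequent among lincRNAs than among the protein-coding genes on the array. In root against leaf 18.2% of lincRNAs and 53.3% of protein-coding genes were called (odds ratio 0.196, two-sided Fisher exact test, adjusted p = 4.77e-13), in inflorescence against leaf 12.6% and 52.2% (odds ratio 0.132, adjusted p = 6.87e-18) and in inflorescence against root 19.6% and 47.8% (odds ratio 0.266, adjusted p = 3.67e-09). Matched on mean signal, the odds ratios were 0.226, 0.148 and 0.231. Leaving out root replicate 3 lowered the odds ratios of root against leaf and inflorescence against root to 0.110 and 0.114, and leaving out inflorescence replicate 3 lowered that of inflorescence against leaf to 0.0640. Genes are not independent replicates, so these p-values describe the genes of this array.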

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

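The counts over regrouped arrays and the comparisons of background and slide were set out before their results were seen. The slide block and the slide grouping of the splits, and the fit without leaf replicate 2, were chosen after seeing the data.

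Probes that did not stand for their gene gave a signal outside the main measurement. Called in the direction opposite to their gene were 9 such probes in root against leaf, 8 in inflorescence against leaf and 3 in inflorescence against root, while 547, 401 and 577 were called the same way. AT1TU069900 had a probe at 4.78 ± 0.81 in root against leaf where the gene was at -3.09. AT2TU032020, a leaf-high lincRNA, had a probe at 4.70 ± 0.77 in inflorescence against leaf where the gene was at -2.61. In inflorescence against root the 3 probes belonged to AT4TU019120, AT4TU045600 and ath-MIR404.

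In inflorescence and root the replicate 3 arrays detected fewer lincRNAs than replicates 1 and 2, 1392 against 2594 and 2674 in inflorescence and 1509 against 2579 and 2876 in root (leaf, with 2730, 501 and 1568 on replicates 1 to 3, was left out here). Weaker signal of all dim probes on slide 2 is argued against by probes matched on slide 1 signal: the matched difference between lincRNA and other probes was on average 1.04 times the median loss of lincRNA probes (0.902 in inflorescence, 1.18 in root). In inflorescence the median lincRNA change was -1.33 against 0.09 for other probes, and the matched difference was -1.20 (95% interval -1.29 to -1.05). In root the matched difference was -1.24 (-1.37 to -1.12). These intervals come from resampling probes, with 1 slide 2 array per organ. They treat probes of the same gene as independent and hold no variation between arrays or plants. The same value, 1.04, is what less lincRNA relative to other RNA in the replicate 3 plants would give, and this remains a candidate explanation. Plants, RNA preparation, labelling and slide all change together at replicate 3 and cannot be told apart.

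Leaf replicate 2 detected the fewest genes, 818 against at least 1860 on every other array. A noisier background could account for this, since its negative control spots had an SD of 8.44 against at most 3.08 on the other 8 arrays. The lowest signal well above background was also higher there, 29.8 against 3.9 to 6.8 on the other arrays. The SD may therefore restate how the count is made, and it does not test a cause on its own. Less labelled RNA was examined through the log2 ratio of bright probes to spike-in spots, -1.29, between the other leaf arrays at -1.43 and 0.14. By the rule set in advance that value goes against less labelled RNA. The ratio cannot decide the question, since a loss shared by gene and spike-in spots leaves it unchanged. The other leaf arrays also lay on different slides, with -1.43 on slide 1 and 0.14 on slide 2. No biological explanation was tested for this single array. Without leaf replicate 2 alone, 565 genes were called in root against leaf and 423 in inflorescence against leaf, with slide as a block alone 654 and 512, and with both changes, over 2393 tested genes, 798 and 697.

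The 6 arrays of each pair of organs allow 10 splits, too few for a share under 0.05. The real splits, fitted on those 6 arrays, gave 474, 363 and 543 genes for root against leaf, inflorescence against leaf and inflorescence against root, and the highest other split gave 0 in each; 1 split, the real one, gave as many. For any difference among the 3 organs, 100 of 280 splits were drawn and 5 gave as many as the real 821 genes, the real one included, so chance was not excluded by that count. The highest other split gave 1394. The other 4 all placed the slide 2 arrays in 1 group, which points to the slide as a structure of the samples, and the highest split without that grouping gave 315. With slide as a block, 96 splits had a value, and among them the real split gave 1268 and the highest other 371. The 4 splits with the slide 2 arrays in 1 group were not fitted with this block, so it does not bear on them.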

How the results depend on the processing

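The common floor, slide 1 alone, the slide block without leaf replicate 2, the leave-one-out values of the gene lists and odds ratios, and the slide block and slide 1 values of the gene lists were chosen after seeing the data. Of the counts and odds ratios under settings other than leaving out an array, 97 stayed within 1.5 times of the value in the report and 37 did not. For 78 pairs of a gene and a comparison, picked for their large folds, 2050 of 2065 values kept the call and 15 lost it, none reversed: 9 with the probes of a gene averaged, 1 with the common floor (AT5TU090930) and 5 for AT4TU024160 in inflorescence against leaf, with no filter and without inflorescence replicate 1, 2 or 3 or leaf replicate 3 (adjusted p from 0.0547 to 0.084). Of 290 pairs that hold these 78 and the list members, called or not, 43 lost a call with the 75th percentile over all probes, 42 at 4-fold, 37 with the median of each array, 24 with normexp, 15 with the probes averaged, 15 with no filter, 14 with quantile normalisation and 14 with the common floor, none reversed. For these shifts the cause was not tested except where the setting itself removes genes or calls. Over all tested genes the median log2 difference was 0.05, -0.20 and -0.26 in root against leaf, inflorescence against leaf and inflorescence against root, and 0.77, 0.42 and -0.36 with the median of each array, so folds near 2 depend on the scaling.

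With the 75th percentile over all probes, inflorescence against leaf had 212 calls, any difference 506 and leaf-preferential genes 56. With the median of each array, inflorescence against leaf had 231 and leaf-preferential genes 36. Normexp with quantile normalisation gave 238, 188 and 220 calls for root against leaf, inflorescence against leaf and inflorescence against root, and 60, 73 and 85 genes preferential to inflorescence, leaf and root. Testing only genes well above background on all 9 arrays, 676 genes, gave 205, 172 and 173 calls, 423 with any difference, and 29 and 43 preferential to inflorescence and root. Averaging probes gave 116 root-preferential genes. Slide as a block gave 1268 genes with any difference. The stricter threshold of at least 4-fold gave 306, 202 and 317 calls and 68, 64 and 116 preferential genes. The common floor, which levels dim signals, gave 320, 239 and 288 calls. Slide as a block without leaf replicate 2 gave 798 calls in root against leaf, 697 in inflorescence against leaf, 1496 with any difference and 248 leaf-preferential genes. Detected on at least 1 array were 3568, 3357 and 3605 genes in inflorescence, leaf and root. Of the list tests 7 passed with an estimated correlation and 27 with fry, against 17.

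The replicate block gave 631, 493 and 616 calls, 1201 genes with any difference, 121, 152 and 228 preferential genes and 19 list calls; it moved no count by over 1.5 times and ended no call among the 290 pairs, but added 9 there and the 2 class shifts in inflorescence against leaf.

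Leaving out each array gave 422 to 565 calls in root against leaf, 307 to 423 in inflorescence against leaf, 415 to 544 in inflorescence against root and 627 to 835 with any difference. Genes preferential to inflorescence, leaf and root ranged from 89 to 123, 98 to 128 and 141 to 198. Detected genes ranged from 1736 to 2760 in inflorescence (highest without replicate 3), 756 to 1918 in leaf (highest without replicate 2) and 1855 to 2883 in root (highest without replicate 3). List calls ranged from 15 to 22. Odds ratios of lincRNAs against protein-coding genes ranged from 0.1098 to 0.223 in root against leaf and 0.114 to 0.2758 in inflorescence against root (both lowest without root replicate 3) and from 0.06401 to 0.1392 in inflorescence against leaf (lowest without inflorescence replicate 3).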

Other observations

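The microRNA precursor families were singled out after their values were seen; the test of neighbouring lincRNAs at a number difference of 10 was set out before its result was seen.

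Of 14 tested precursors of MIR169, whose microRNAs target NF-YA transcripts, 9 were called lower in inflorescence than in leaf and 6 lower than in root, none were called higher, and the other 5 and 8 did not pass. No test was run on the family as a set. Of the precursors, ath-MIR169d, ath-MIR169f, ath-MIR169j and ath-MIR169m were well above background on all 3 inflorescence arrays, and the others on 2 or fewer, so most folds are not exact. Of those measured on all inflorescence and leaf arrays, ath-MIR169d differed from leaf by -2.65 ± 0.53, ath-MIR169j by -4.75 ± 0.57 and ath-MIR169m by -4.39 ± 0.61. With the 75th percentile over all probes, quantile normalisation, the median of each array and normexp, the calls lower than leaf were 9, 9, 8 and 8 and those lower than root 10, 9, 7 and 0. Near-identical family members can share signal on a probe. All 3 precursors of MIR398, whose microRNAs target copper/zinc superoxide dismutase transcripts, were called lower in inflorescence than in leaf and root, under each of these scalings too. Their inflorescence signals were at background, with ath-MIR398a and ath-MIR398c not well above it on any array and ath-MIR398b on 1 of 3.

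Of 6 MIR166 precursors, 4 were called higher in root than in leaf, 3 of them with leaf well above background on 2 of 3 arrays. In inflorescence against root 1 was called lower (ath-MIR166b) and 1 higher (ath-MIR166f), and ath-MIR166f was also called higher in inflorescence than in leaf, with no leaf or root array well above background. With the 75th percentile over all probes 1 of the 6 was called and with normexp none. Of 4 MIR167 precursors 3 were called lower in root than in leaf, but with the median of each array 1 was called lower and 1 higher, and with normexp 2 were called lower.

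lincRNAs are numbered along the chromosomes, and neighbours in number had related organ patterns. Over 194 pairs with numbers differing by 10, the median correlation of organ means was 0.512, against a median of 0.177 and a highest of 0.494 over 1000 random re-pairings. At a difference of 20 the median was 0.293 (highest random 0.596), at 30 to 50 it was 0.360 (0.467) and at 60 to 100 it was 0.223 (0.352), so only the closest pairs lay above every re-pairing, by a narrow margin. Shared transcription of adjacent units, or a single transcript divided into several units, may account for this, and the values do not separate these.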
